A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

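RNA from 4 pairs of yeast cultures was measured on 4 two-colour Agilent arrays (design 016322), 2 for sorbitol against YPD and 2 for glucose against YPD. Per the labels' protocols, 10 µg of total RNA per sample was reverse transcribed with Cy3- or Cy5-labelled dCTP. Channel 1 is Cy3 and channel 2 is Cy5, and the samples in each channel were taken from the labels. The arrays of a stress have opposite dye orientation, so that a dye effect on a gene cancels in the mean of the 2. All 4 arrays lay on 1 slide, so no slide effect could be fitted.

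The deposited scanner files give the intensity of each spot on a linear scale (mean signal and local background in each channel) and, per the file headers, were made with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 8.5.1.1. The same files hold background-subtracted, dye-normalized signals and a log10 ratio of Cy5 over Cy3, computed by that software per the file headers. They also hold flags for spots above background, saturated or uneven. The deposited series matrix holds log2 values whose making is not given in the sources used here. Set against the scanner software's log2 ratios, they had a slope of 0.97, -0.97, 0.97 and -0.98 for sorbitol replicates 1 and 2 and glucose replicates 1 and 2, so they run as stress over YPD on every array. Their medians were -0.01, -0.01, 0.01 and 0.04, and 339 to 400 of 12512 spots were blank. Their background correction and centring stay unknown, and they were used only as an alternative.

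Intensities were background-corrected with normexp (offset 50) on all 13048 spots and normalized within each array by loess, with control spots and outlier spots at weight 0, in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Of the 12512 gene spots, 62 were outliers on sorbitol replicate 1 and 6 on the other arrays together, and these were left out. No gene spot was saturated. Ratios were turned to stress over YPD, the 2 spots of each of 6256 probes were averaged, and probes were kept where at least 1 channel was well above background on both arrays of at least 1 stress (6214 probes). The probes of a gene were averaged, which gave 6184 genes. Only 28 genes had several probes, and the means of a gene's probes differed by up to 0.79 in sorbitol (YPR089W) and 1.24 in glucose (TC21605). All genes named in the report except HOT1 were measured in both channels. Gene symbols were taken by locus tag from an NCBI RefSeq table of assembly R64. Of 6227 names, 5738 matched and 489 kept the name in the file. The probe annotation names more than 1 gene for 165 of the kept probes, and values of such genes are uncertain. Probe positions are those of the files (sacCer1).

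A linear model with 1 mean per stress was fitted over all 4 arrays (2 residual degrees of freedom, 3.33 prior degrees of freedom), with moderated statistics (lmFit and eBayes), 2-sided p-values and Benjamini-Hochberg adjustment over the 6184 genes of each comparison. The comparisons were each mean against 0 and glucose minus sorbitol. With 2 arrays per stress, the number of arrays limits the precision. On data simulated for the sorbitol comparison with the spread of the real 6184 genes, 10% of 50 genes changed by 0.5 (log2), 88% of 50 changed by 1, 98% of 50 changed by 2 and all 50 changed by 3 were called, with 12 calls among 5984 unchanged genes. Only 200 genes were changed there, while 3830 were called in the real sorbitol data. The adjustment is less strict where more genes change, so these shares do not give the power in the real data. Gene sets were 34 lists fixed, like the design, the alternatives and the rule for named genes, before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists of a comparison, and again with an estimated correlation, with which no list was called (lowest adjusted p 0.67 in sorbitol, 0.58 in glucose and 0.84 for the difference). The latter test rests on the 2 residual degrees of freedom, which leaves it little power. For the difference, the HOG pathway had an estimated correlation of 0.0106, close to the preset one. Its camera adjusted p still went from 0.00726 to 0.84. A call lost in this way does not by itself show that the genes of a list are strongly correlated. Over the 34 lists the estimates ran from -0.28 (alpha cell markers) to 0.74 (ribosome biogenesis). General stress genes had 0.71, cytoplasmic ribosomal proteins 0.70 and Hot1-associated genes 0.40. These estimates also rest on 2 residual degrees of freedom. Where the estimate is far above the preset 0.01, camera's p-values at the preset correlation may be much too small. In simulated data camera called the 1 list that was shifted and none of the other 33. The listed gene HSP150 was not matched. A list's median, mean and camera direction differed in sign for 2, 1 and 2 of the 34 lists in the 3 comparisons, none of them called.

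Named genes are, per comparison, the 10 with the largest increase and the 10 with the largest decrease among genes with a symbol that passed and had the same sign on both arrays (for the difference, both glucose arrays above or below both sorbitol arrays). HOT1, every Hot1-associated gene and up to 4 members of smallest p per described list were added. MSN4, SOF1 and RGT2, which complete a count, were named after their values were seen.

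The alternatives were no background correction, the scanner software's signals, median centring, an offset of 16, no filter and a strict filter on dim probes, the series matrix, the brightest probe per gene, a trend or robust option in eBayes, each stress fitted alone, the replicate number as a block, each array left out, a 2-fold minimum, and fry and an estimated correlation for lists. Scaling to 10 spike-in controls and leaving out probes of several genes were added after seeing the data. In the first of these, each array's loess-normalized log ratios were shifted by its mean spike-in log ratio, taken after median centring, less the mean over the 4 arrays. All genes of an array thus move alike, and a list's log ratio relative to the other genes stays the same. Camera compares moderated t values, whose standard errors differ between genes, so its result can still change. A camera call kept with this scaling is therefore no separate support for that call. A first version shifted median-centred gene values instead and was replaced so that only 1 choice differed.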

Results

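Transcript levels were measured in budding yeast (Saccharomyces cerevisiae, strain background W303 1-a) carrying a deletion of HOT1, the gene of a transcription factor that acts in the response to high osmolarity. Exponentially growing cells at an OD600 of 0.8 were kept in YPD, a rich medium with glucose, or were exposed for 30 minutes to 1 M sorbitol, a sugar alcohol, or to 20% (w/v) glucose. On each of 4 two-colour arrays the RNA of a stressed sample was hybridised together with the RNA of an unstressed YPD sample, giving 2 arrays per stress. The labels call the arrays of a stress biological replicates. Replicate 1 carried the stressed RNA in Cy5 and replicate 2 carried it in Cy3. The median probe signal was between 108 and 523 times the median background in the 8 channels, and between 97.6% and 99.3% of the gene spots lay well above background. Values are log2 ratios of stress over YPD, relative to the genes of the same array, with the SD between the 2 arrays, unless another quantity is named. A gene was called when limma's adjusted p was under 0.05, and 6184 genes were tested.

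HOT1 itself was not well above background in any of the 8 channels. Its only probe lies on chromosome XIII, from 607856 to 607915 in the sacCer1 build, and its signal was between 31.8 and 132 units. In each channel this placed it between the 0.0959th and the 1.25th percentile of all probes and below the 95th percentile of the negative control spots. The labels do not state which part of the gene was removed, and no strain with an intact HOT1 was analysed here, so none of the responses below was set against one.

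The first comparison asked which transcripts changed in 1 M sorbitol. The largest increases were those of HSP12, a small membrane-associated heat shock protein (8.52 ± 1.11), MPC3, a subunit of the mitochondrial pyruvate carrier (6.53 ± 1.24), DDR2, a stress-induced gene (6.26 ± 0.42), HXT5, a hexose transporter (6.01 ± 0.19), and ALD3, an aldehyde dehydrogenase (5.87 ± 0.36). They were followed by RGI2 (5.65 ± 0.12), PRR2 (5.61 ± 0.29), the Hsp70 chaperone gene SSA4 (5.40 ± 0.83), the lactate dehydrogenase gene CYB2 (5.27 ± 0.28) and SPG4 (5.24 ± 0.09). For HSP12 the mean change was 367-fold (adjusted p = 0.000618). The decreases were smaller. BSC1 stood at -2.65 ± 0.02, and the ribosomal RNA processing genes UTP20, RRP5 and KRE33 at -2.51 ± 0.46, -2.47 ± 0.30 and -2.37 ± 0.05. RPS0B, a protein of the small ribosomal subunit, stood at -2.48 ± 1.40, the pheromone-regulated PRM7 at -2.47 ± 0.22 and the polyamine exporter gene TPO2 at -2.45 ± 0.95. FAR1, an inhibitor of the cell cycle kinase, stood at -2.37 ± 0.03, the pseudouridine synthase gene PUS7 at -2.35 ± 0.37 and VTC3, of the polyphosphate polymerase, at -2.32 ± 0.01.

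Of the 9 genes associated with Hot1 in the list fixed beforehand, 8 rose in sorbitol (8 also when adjusted over the list alone). They were STL1, the glycerol-proton symporter (4.75 ± 0.06, 26.8-fold), GPP2 and GPD1 of glycerol synthesis (4.90 ± 0.25 and 2.95 ± 0.16), the catalase gene CTT1 (4.94 ± 0.22), RTC3 (4.38 ± 0.27), FMP48 (1.94 ± 0.04), PHM8 (1.71 ± 0.21) and HSP12. CHA1, a serine and threonine deaminase, stood at 0.21 ± 0.18 and was not called (adjusted p = 0.38). The list moved up as a set (camera, adjusted p = 0.000332), with an adjusted p = 0.67 with an estimated correlation.

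Genes of the general stress response rose together: 34 of 36 members were called up and none down (35 up when adjusted over the list alone), with a list median of 3.27 and a camera adjusted p = 3.23e-11. Examples were HSP26 (4.26 ± 0.16), GRE1 (4.70 ± 0.01), the hexokinase gene HXK1 (4.47 ± 0.26) and HSP78 (2.74 ± 0.20). Among heat shock chaperones 19 of 26 rose and none fell (19 and 0 over the list alone), among them BTN2 (2.85 ± 0.14) and FES1 (2.12 ± 0.04; camera adjusted p = 1.44e-05). Of 20 trehalose and glycogen genes 17 rose and 1 fell (18 and 2 adjusted over the list alone), including TSL1 (2.85 ± 0.08) and TPS1 (2.38 ± 0.14) of trehalose synthesis (camera adjusted p = 0.000283). The oxidative stress list had 14 of 28 members up and 2 down, as it did when adjusted over the list alone (camera adjusted p = 0.00624), with GRX2 at 3.59 ± 0.01 and the mitochondrial peroxiredoxin gene PRX1 at 3.63 ± 0.20. These lists share members, so their calls are not independent of each other in any comparison. Among others, general stress shares HSP26, HSP78 and SSA4 with heat shock, TPS1 and TSL1 with trehalose and glycogen, and CTT1 with oxidative stress. HSP12 and CTT1 are also in the list of Hot1-associated genes. With an estimated correlation each of these lists had an adjusted p = 0.67. With spike-in scaling, an alternative chosen after seeing the data, 29 general stress genes were called up and 3 down (median 1.91), 12 heat shock genes up and 7 down (0.48), 7 trehalose and glycogen genes up and 4 down (0.41), and 9 oxidative stress genes up and 13 down (-0.41). The median of all genes was then -1.36, and camera still called each of these lists up relative to the other genes.

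Genes for carbon sources other than glucose also rose: 21 of 25 were called up and 3 down (22 and 3 adjusted over the list alone; camera adjusted p = 2.10e-05). JEN1, a lactate and pyruvate transporter, stood at 3.51 ± 0.15, the acetaldehyde dehydrogenase gene ALD4 at 3.37 ± 0.01 and CAT8, a transcription factor of gluconeogenesis, at 2.32 ± 0.09. Smaller shifts upward were called for the tricarboxylic acid cycle (11 of 18 up, 2 down, 12 and 2 over the list alone; adjusted p = 0.0288), the respiratory chain and ATP synthase (16 of 36 up, 3 down, 16 and 3 over the list alone; adjusted p = 0.0299), sporulation genes (13 of 20 up, 3 down, 14 and 3 over the list alone; adjusted p = 0.0299) and the proteasome (11 of 33 up, 0 down, and 7 up when adjusted over the list alone; adjusted p = 0.0398). CIT3 (1.70 ± 0.09), CYC7 (4.13 ± 0.59), DMC1 (2.81 ± 0.05) and RPN4, the transcription factor of the proteasome genes (2.76 ± 0.00), were members of these lists. The camera call of the proteasome was lost without sorbitol replicate 2, with median centring and with the series matrix values (adjusted p = 0.213, 0.711 and 0.0508). With median centring the calls of the oxidative stress, tricarboxylic acid cycle and respiratory chain lists were lost too (adjusted p = 0.082, 0.193 and 0.247). With spike-in scaling the medians of the proteasome, tricarboxylic acid cycle, respiratory chain and sporulation lists were negative (-1.06, -0.77, -0.96 and -0.60), though above the -1.36 of all genes. Camera still called the respiratory chain and sporulation lists up (adjusted p = 0.0223 and 0.00474). It no longer called the proteasome and the tricarboxylic acid cycle (adjusted p = 0.757 and 0.134). With the same scaling the list of other carbon sources had 8 members up and 9 down, with a median of 0.08, and stayed called up (camera adjusted p = 4.53e-10). Each of these lists had an adjusted p = 0.67 with an estimated correlation.

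Genes of ribosome production fell in sorbitol. Of 65 ribosome biogenesis genes 55 fell and none rose (55 also adjusted over the list alone), with a median of -1.24 and a camera adjusted p = 5.08e-12. TSR1 stood at -2.11 ± 0.20 and UTP22 at -2.01 ± 0.25. Of 26 genes of RNA polymerases I and III 20 fell and 1 rose (22 and 1 over the list alone; camera adjusted p = 2.07e-05), with RPA135 at -2.25 ± 0.10. Of 136 cytoplasmic ribosomal protein genes 44 fell, 2 rose and 90 did not pass (23 down and 2 up when adjusted over the list alone; camera adjusted p = 2.20e-06). RPS7A stood at -1.48 ± 0.06 and RPL6B at -1.83 ± 0.21, while RPL15B was among those that rose (0.95 ± 0.01), though it was called lower with spike-in scaling (-0.41). The median of this list was -0.32 on replicate 1 and -1.66 on replicate 2, and 123 of its genes were among the brightest 5% of all genes, where the log ratios of the 2 dye orientations differed most. Amino acid synthesis genes (21 of 57 down, 6 up, 18 and 5 over the list alone; camera adjusted p = 0.0299) and the iron regulon (11 of 24 down, 2 up, 11 and 2 over the list alone; camera adjusted p = 0.0404) were also called down. HIS1 stood at -1.91 ± 0.01 and the iron reductase gene FRE1 at -1.89 ± 0.17, whereas HMX1, a haem oxygenase, rose (2.82 ± 0.29). The amino acid call was lost without sorbitol replicate 1 and the iron call without replicate 2 (adjusted p = 0.0689 and 0.0506). With spike-in scaling the medians of the ribosomal protein, amino acid and iron lists were lower still (-2.37, -1.68 and -1.89), with 123, 54 and 23 members called down. Camera, which compares a list with the array's other genes, no longer called them (adjusted p = 0.757, 0.071 and 0.223). Relative to the median of all genes, which was -1.36 with this scaling, the lists had not moved. The ribosome biogenesis and RNA polymerase lists stayed called down (camera adjusted p = 0.000269 and 0.0207). The adjusted p = 0.67 with an estimated correlation held for each of these lists as well.

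In all, limma called 2006 genes higher and 1824 lower in sorbitol, and 1040 and 656 of these changed at least 2-fold. All changes are relative to the array's own genes: when each array was scaled to its added spike-in controls, an alternative chosen after seeing the data, the median of all genes moved to -1.36 in sorbitol and the calls became 394 higher and 5053 lower, and 930 genes called higher were then called lower. The count fell to 1969 genes without sorbitol replicate 1 and to 2216 without replicate 2.

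The second comparison asked which transcripts changed in 20% glucose. HSP12 again had the largest mean increase (7.82 ± 1.89, 225-fold), followed by THI4, of thiamine synthesis (6.22 ± 0.63), ALD3 (6.18 ± 1.19), SSA4 (5.94 ± 1.60) and HXT5 (5.63 ± 1.22). Next came the reductase gene GRE2 (48.6-fold), FMP45 (5.39 ± 1.16), DDR2 (5.35 ± 1.40), CTT1 (5.30 ± 1.13) and GPP2 (5.18 ± 1.01). The largest decrease was that of SYO1, an import adaptor for ribosomal proteins (-4.67 ± 0.20, adjusted p = 0.000254). AAH1, the adenine deaminase, stood at -4.35 ± 0.15, and the ribosomal RNA processing genes RRP5, UTP23, MRD1 and KRE33 at -4.21 ± 0.02, -4.00 ± 0.14, -3.88 ± 0.30 and -3.83 ± 0.34. RPA190, the largest subunit of RNA polymerase I, stood at -3.88 ± 0.33 and the CTP synthase gene URA7 at -3.86 ± 0.05. Next were the ribose-5-phosphate isomerase gene RKI1 at -3.67 ± 0.39 and the hexose transporter HXT6 at -3.71 ± 1.33. The HXT6 probe is annotated to more than 1 gene, so its value cannot be assigned to HXT6 alone.

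All 9 Hot1-associated genes rose in glucose (9 also adjusted over the list alone). STL1 stood at 2.50 ± 0.54, GPD1 at 3.74 ± 1.26, RTC3 at 4.07 ± 0.78, FMP48 at 2.37 ± 0.27, PHM8 at 2.20 ± 0.08 and CHA1 at 1.14 ± 0.47, beside the values of HSP12, CTT1 and GPP2 above. The list was called by camera (adjusted p = 0.000107), with an adjusted p = 0.58 with an estimated correlation. The wider list of glycerol synthesis and transport had 8 of 17 genes up and 3 down (8 and 3 over the list alone), among them YPR1 (3.04 ± 0.32), DAK1 (3.27 ± 0.51) and GCY1 (2.00 ± 0.07). Its camera adjusted p = 0.0479 became an adjusted p = 0.66 with an estimated correlation. The call was also lost with median centring, the scanner software's signals, an offset of 16, a trend in eBayes and without glucose replicate 1 (adjusted p between 0.0508 and 0.143).

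**Figure D1:**
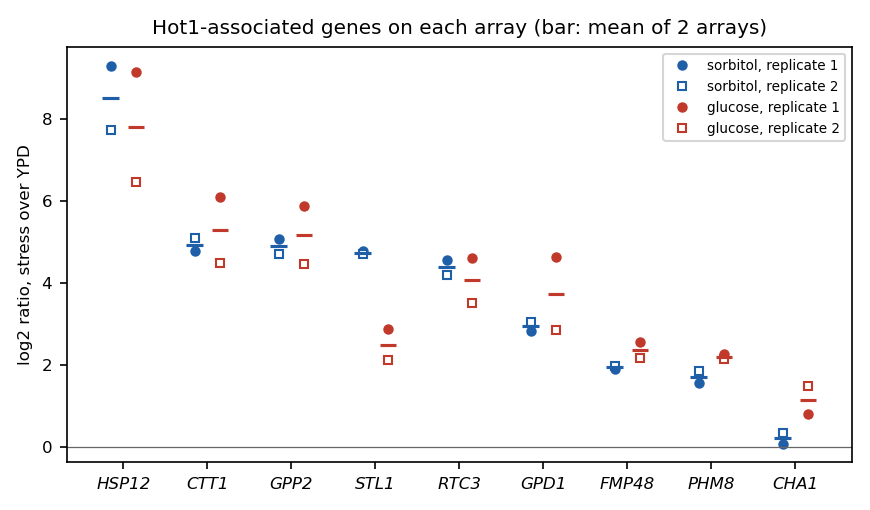
Log2 ratio of stress over YPD (vertical axis) of the 9 Hot1-associated genes, with filled circles for replicate 1, open squares for replicate 2 and a bar for their mean, in blue for sorbitol and red for glucose. STL1 lies at 4.75 in sorbitol and at 2.50 in glucose, and CHA1 is the gene closest to 0 in both.

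General stress genes rose in glucose as well (33 of 36 up, 1 down, the same counts adjusted over the list alone), with a median of 3.0 (camera adjusted p = 1.16e-09). GRE3, an aldose reductase, stood at 3.76 ± 0.01 and SPI1 at 4.58 ± 0.80, and MSN4 was the member that fell (-0.47, adjusted p = 0.0401). Heat shock chaperones had 23 of 26 members up and none down (24 up over the list alone; camera adjusted p = 1.24e-07), with BTN2 at 2.70 ± 0.10 and FES1 at 2.45 ± 0.14. Of the oxidative stress genes 18 of 28 rose and 1 fell (18 and 1 over the list alone; camera adjusted p = 0.00122), including TRX2, a thioredoxin (2.52 ± 0.19). Of the trehalose and glycogen genes 12 of 20 rose and 2 fell (12 and 2 over the list alone; camera adjusted p = 0.0261), with UGP1 at 2.56 ± 0.62 and NTH1 at 2.17 ± 0.48, and this call was lost without glucose replicate 1 (adjusted p = 0.139). With an estimated correlation the adjusted p was 0.58 for the first 3 of these lists and 0.70 for trehalose and glycogen.

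Proteasome genes rose in glucose, with 26 of 33 members up and none down (26 and 0 over the list alone) and a median of 0.66 (camera adjusted p = 1.97e-05). PRE4 stood at 1.06 ± 0.01, RPT3 at 0.96 ± 0.13 and RPN4 at 1.70 ± 0.24. With median centring in place of loess the median was 0.18 and the call was lost (adjusted p = 0.25). Autophagy and vacuolar protease genes had 18 of 23 members up and none down (19 up over the list alone; camera adjusted p = 9.76e-05), among them ATG39 (2.53 ± 0.33), ATG14 (1.77 ± 0.00) and the vacuolar protease gene PEP4 (1.68 ± 0.36). Genes for other carbon sources (19 of 25 up, 3 down, 20 and 3 over the list alone; camera adjusted p = 0.00011), sporulation genes (15 of 20 up, 2 down, 15 and 2 over the list alone; camera adjusted p = 0.000928) and genes under nitrogen catabolite repression (13 of 23 up, 3 down, 14 and 3 over the list alone; camera adjusted p = 0.03) were called up too. The proline permease gene PUT4 stood at 4.70 ± 1.01, ALD4 at 3.84 ± 0.56, GAL10 at 2.54 ± 0.36 and DIT2 at 2.37 ± 0.26, while GAP1, the general amino acid permease, fell (-1.64 ± 0.06). With an estimated correlation the adjusted p was 0.66 for nitrogen catabolite repression and 0.58 for the other lists of this paragraph.

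Ribosome biogenesis genes fell almost without exception in glucose: 64 of 65 were called down and none up (64 adjusted over the list alone), with a median of -2.64, or 6.22-fold lower (camera adjusted p = 6.09e-21). UTP10 stood at -3.23 ± 0.01, NOP2 at -3.17 ± 0.22 and TSR1 at -2.74 ± 0.04, and SOF1 was the member that did not pass (-0.17, adjusted p = 0.433). Of the RNA polymerase I and III genes 23 of 26 fell and 2 rose (23 and 2 over the list alone; camera adjusted p = 2.59e-07), with RPA43 at -3.63 ± 0.08 and RPA135 at -3.55 ± 0.07. Cytoplasmic ribosomal protein genes had 62 of 136 members down and 1 up (54 down and 0 up over the list alone; camera adjusted p = 9.01e-09), with RPL7B at -2.69 ± 0.25 and RPL31B at -2.14 ± 0.10, and list medians of -0.43 on replicate 1 and -2.0 on replicate 2. Amino acid synthesis (32 of 57 down, 7 up, 32 and 7 over the list alone; camera adjusted p = 0.000319), the phosphate regulon (11 of 18 down, 2 up, 11 and 2 over the list alone; camera adjusted p = 0.0057) and genes of the G2 and M phases (19 of 28 down, 2 up, 19 and 3 over the list alone; camera adjusted p = 0.00127) were called down as well. LEU9 stood at -2.62 ± 0.05, VTC3 at -2.95 ± 0.10, the daughter cell gene EGT2 at -2.64 ± 0.24 and AMN1 at -2.48 ± 0.19, while PHM7 and PHM8 of the phosphate list rose (4.93 ± 0.80 and 2.20 ± 0.08). With an estimated correlation the adjusted p was 0.67 for the ribosomal proteins and 0.58 for the other lists that fell.

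**Figure D2:**
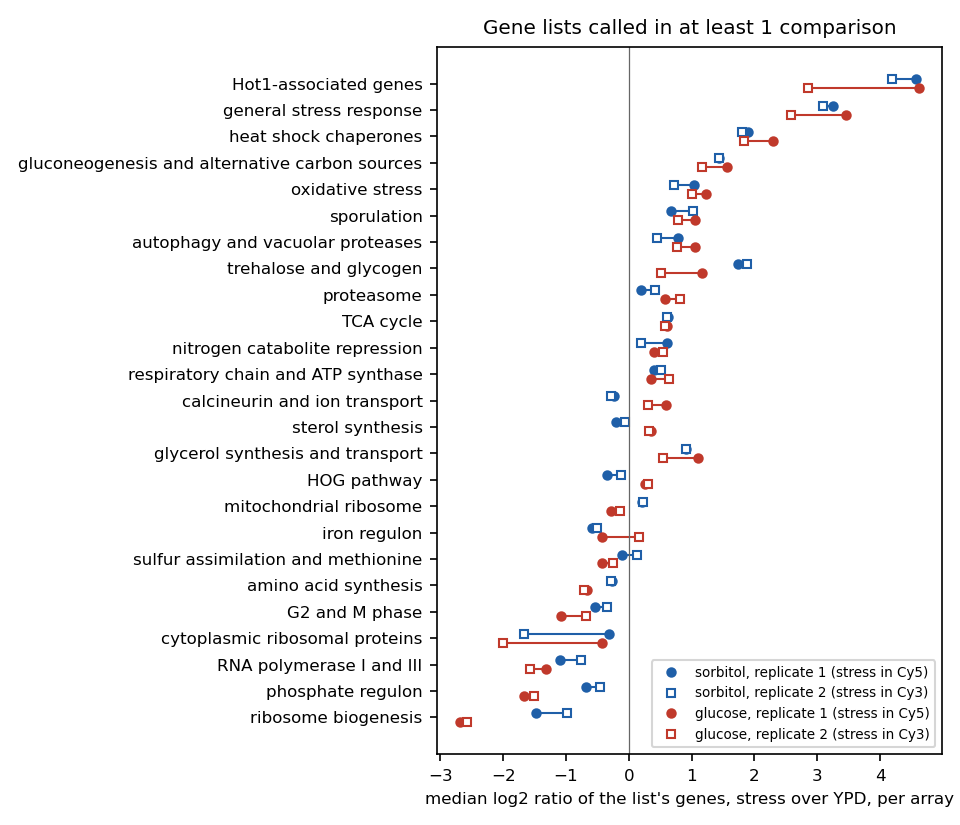
Median log2 ratio of stress over YPD (horizontal axis) of each gene list called in at least 1 comparison, per array, with filled circles for replicate 1, open squares for replicate 2 and a line joining them, in blue for sorbitol and red for glucose. The ribosome biogenesis medians are -1.47 and -0.99 in sorbitol and -2.69 and -2.57 in glucose, and the cytoplasmic ribosomal protein medians of the 2 replicates lie far apart in both stresses.

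In all, 1961 genes were called higher and 1837 lower in glucose, of which 889 and 878 changed at least 2-fold. Scaled to the spike-in controls, the median of all genes was -0.11 and the calls were 1639 higher and 2184 lower.

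The third comparison set the 2 responses against each other, as the title of the series does. Across genes, which are not independent replicates, the mean log2 ratios in sorbitol and glucose had a Pearson r of 0.78 and a Spearman rho of 0.76, and 78.6% of genes had the same sign. The correlation between arrays was 0.92 within sorbitol and 0.89 within glucose, and between 0.68 and 0.80 across the stresses. Both stresses raised 1442 genes, against 636 for independent lists, and lowered 1228, against 542. The labels give the stresses separately named YPD samples. Another 82 genes rose in sorbitol and fell in glucose, and 62 did the reverse. The difference between the stresses was called for each of these 144 genes. This is no separate support, since both stresses share 1 standard error per gene and opposite calls already imply a large difference. The shared and opposite counts and the share of the same sign are relative to the array's own genes. With spike-in scaling only 394 genes were called higher in sorbitol, fewer than the 1442 raised by both stresses above. The counts therefore do not hold under that scaling.

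The genes that were lowest in glucose relative to sorbitol were led by sugar transport genes. HXT7 and HXT6, hexose transporters with high affinity, stood at 2.17 ± 0.53 and 1.84 ± 0.22 in sorbitol and at -3.54 ± 1.30 and -3.71 ± 1.33 in glucose, differences of -5.71 (95% interval -7.30 to -4.12) and -5.55. Both probes are annotated to more than 1 gene. HXT4 (1.61 ± 0.61 and -2.47 ± 0.03; difference -4.08, adjusted p = 0.00949) and HXT2 (0.58 ± 0.11 and -3.17 ± 0.67; difference -3.75, adjusted p = 0.00992), with probes of their own, went the same way, and HXT2 was not called in sorbitol. MTH1, a regulator of hexose transporter expression, rose in sorbitol (3.70 ± 0.07) and fell in glucose (-1.36 ± 1.00; difference -5.06). The respiratory growth genes RGI1 and RGI2 differed by -4.67 and -4.37, AHT1 by -3.78, the protein kinase gene MRK1 by -3.38 and the acid phosphatase gene PHO12, with a probe shared by another gene, by -3.34. The hexose transporter list as a whole was not called (camera adjusted p = 0.374), with 6 of 19 members lower in glucose and 1, RGT2, higher. With spike-in scaling 12 members were higher and 4 lower (median 1.14, against 1.16 for all genes). Camera then called the list down (adjusted p = 0.000928), though relative to all genes its log ratios had not moved.

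In the other direction, ARO10 and ARO9, of aromatic amino acid breakdown, were higher in glucose by 2.64 (95% interval 2.14 to 3.14) and 2.21. The drug exporter gene ATR1 was higher by 2.60, the cell wall gene NCW2 by 2.56, PUN1 by 2.38, TPO2 by 2.29 and NCA3 by 2.26. VPS36, of endosomal sorting, was higher by 2.21, the chitin synthase gene CHS1 by 2.20 and the sodium pump gene ENA2, whose probe is shared with another gene, by 2.13. TPO2 fell in sorbitol and stood at -0.16 ± 0.44 in glucose, where it was not called (adjusted p = 0.705). Of the Hot1-associated genes STL1 alone differed, with a value 4.74-fold lower in glucose (difference -2.24, 95% interval -2.96 to -1.53, adjusted p = 0.0131). The intervals of the others were wide, as for HSP12 (-3.13 to 1.72) and GPD1 (-0.66 to 2.24). Without glucose replicate 2, GPD1 and CTT1 were called higher in glucose as well (1.68 and 1.15), and without glucose replicate 1 CHA1 was (1.27). With spike-in scaling 6 genes of this list were called higher in glucose and 1 lower.

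Relative to the genes of the same array, ribosome biogenesis genes fell further in glucose than in sorbitol: 46 of 65 were called lower and none higher (54 lower over the list alone), with a median difference of -1.25 (camera adjusted p = 1.97e-14). With spike-in scaling the median difference was -0.0346, against 1.16 for all genes, with 10 members higher and 12 lower. Camera still called the list down relative to the other genes (adjusted p = 4.79e-34). That is no separate support, since the list's log ratios relative to those genes had not moved. NOP7 differed by -2.60, LTV1 by -2.40 and KRR1 by -1.83. RNA polymerase I and III genes (10 of 26 lower, 0 higher, 12 and 0 over the list alone; camera adjusted p = 0.00201), mitochondrial ribosomal proteins (15 of 56 lower, 0 higher, 20 and 0 over the list alone; camera adjusted p = 8.44e-06), sulfur assimilation and methionine genes (10 of 25 lower, 1 higher, 12 and 2 over the list alone; camera adjusted p = 0.0036) and G2 and M phase genes (13 of 28 lower, 3 higher, 14 and 3 over the list alone; camera adjusted p = 0.0134) were also lower in glucose. RPA43 differed by -1.96, MRPS17 by -1.31, MET28 by -2.57, MET6, the methionine synthase, by -1.72 and EGT2 by -2.80. Each of these lists had an adjusted p = 0.84 with an estimated correlation. With spike-in scaling the median differences of the last 4 lists turned to 0.60, 0.74, 0.59 and 0.50, below the 1.16 of all genes. Camera still called the RNA polymerase, sulfur and G2 and M lists down (adjusted p = 0.000498, 6.29e-06 and 0.000106). The call of the mitochondrial ribosomal proteins was lost (camera adjusted p = 0.0759).

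Lists higher in glucose were those of calcineurin and ion transport (8 of 22 higher, 0 lower, 9 and 0 over the list alone; camera adjusted p = 0.000185), sterol synthesis (6 of 25 higher, 0 lower, 6 and 0 over the list alone; camera adjusted p = 0.00146), the HOG pathway, which signals high osmolarity (6 of 24 higher, 1 lower, 10 and 1 over the list alone; camera adjusted p = 0.00726), the proteasome (2 of 33 higher, 1 lower, 0 and 0 over the list alone; camera adjusted p = 0.00201) and heat shock chaperones (2 of 26 higher, 1 lower, 2 and 1 over the list alone; camera adjusted p = 0.0309). RCN2, of the calcineurin regulators, was higher by 1.42, CMK2 by 1.24, ERG13 and ERG10 of sterol synthesis by 1.29 and 1.22, the phosphatase gene PTP3 by 1.39, SKO1 by 0.95, RPN2 by 0.83 and HSP82 by 0.96. RPN4 was the proteasome list member that was lower in glucose (-1.06). The adjusted p = 0.84 with an estimated correlation held for each of these 5 lists. With median centring in place of loess the calls of the sterol, proteasome, heat shock and G2 and M lists were lost (adjusted p = 0.147, 0.321, 0.586 and 0.199). Without glucose replicate 1 those of the heat shock, G2 and M, and sulfur lists were lost (adjusted p = 0.374, 0.0934 and 0.0505). The heat shock call was also lost with the scanner software's signals, with the series matrix values, without sorbitol replicate 2 and with spike-in scaling (adjusted p = 0.163, 0.0762, 0.13 and 0.452). General stress genes were not called as differing (camera adjusted p = 0.98), with a median difference of -0.13. With spike-in scaling the median difference was 1.09, against 1.16 for all genes, with 17 members higher and 1 lower. Camera then called the list down (adjusted p = 0.0205), though relative to all genes its log ratios had not moved.

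**Figure D3:**
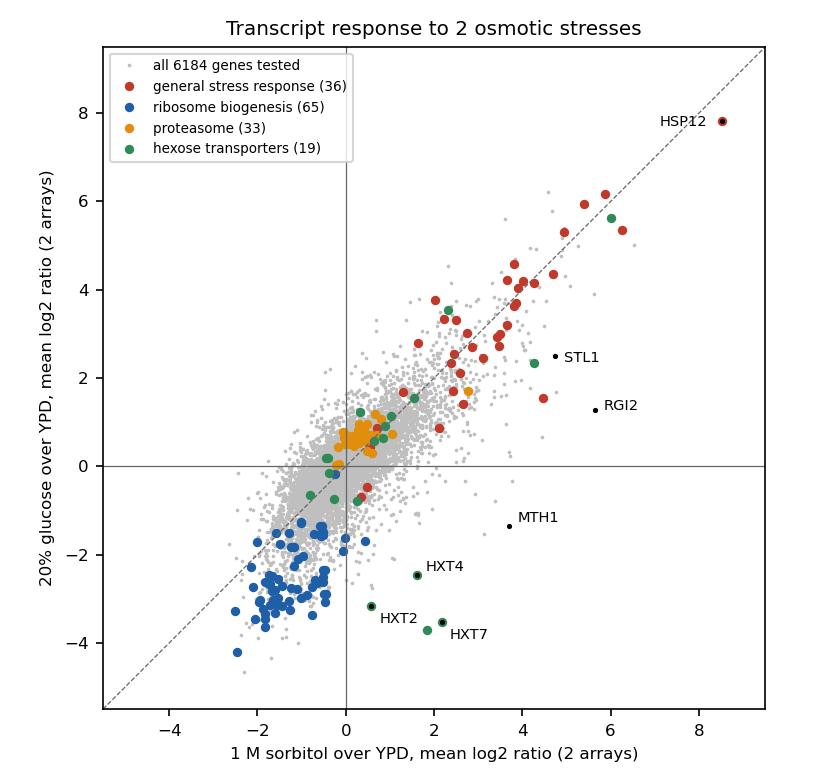
Mean log2 ratio over YPD in sorbitol (horizontal axis) and in glucose (vertical axis), each over 2 arrays, for all 6184 genes in grey and for 4 gene lists in colour; the dashed line marks equal responses. The 65 ribosome biogenesis genes lie mostly below the dashed line (median difference -1.25), and HXT2, HXT4, HXT7 and MTH1 lie below 0 in glucose and above 0 in sorbitol, where HXT2 was not called.

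The test of the difference called 520 genes higher and 843 lower in glucose than in sorbitol, 247 and 549 of them by at least 2-fold. This count changed with the arrays kept, with the model and with the normalization. Leaving out an array left its stress with 1 array and 1 dye orientation, so a dye effect no longer cancelled. The spread then came from the other stress alone. A lower count therefore does not show that the array left out carried the result. With the replicate number as a block the count was 2841 (1204 higher, 1637 lower). It was 167 without sorbitol replicate 1, 67 without sorbitol replicate 2 and 870 without glucose replicate 2, and with median centring limma called 0 genes, with 1801 at an unadjusted p under 0.05. Scaled to the spike-in controls, 4872 genes were higher and 125 lower in glucose, with a median difference of 1.16.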

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

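The tests of a scale factor, of the scaling to the array's genes, of the spike-in offsets and of the size of the response and brightness behind the replicate deviations were chosen after those results were seen. The tests of probe sequence and of normalization were written down first, but spike-in scaling was weighed with the latter only afterwards. A further test written first, of probes shared between genes, was dropped because no ribosome biogenesis probe is annotated to more than 1 gene.

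A direct test of the difference between the stresses called 1363 genes. Relative to the array's own genes, 144 of these were called in opposite directions by the 2 stresses. Differences of the gene list medians, glucose minus sorbitol, called by camera were 0.52 for the HOG pathway, 0.42 for heat shock chaperones, 0.45 for sterol synthesis, 0.68 for calcineurin and ion transport, 0.39 for the proteasome, -0.48 for the mitochondrial ribosome, -1.25 for ribosome biogenesis, -0.62 for RNA polymerases I and III, -0.62 for sulfur assimilation and methionine, and -0.72 for the G2 and M phases. None of these 10 lists was called with an estimated correlation (adjusted p = 0.84), and with spike-in scaling the medians of the mitochondrial ribosome, RNA polymerase, sulfur and G2 and M lists turned to 0.74, 0.60, 0.59 and 0.50. These medians lie below the 1.16 of all genes. With this scaling camera still called the RNA polymerase, sulfur and G2 and M lists down, but not the mitochondrial ribosome. The single genes that differed most were ARO10 (2.64), ATR1 (2.60), NCW2 (2.56), PUN1 (2.38), TPO2 (2.29), NCA3 (2.26), ARO9 (2.21), VPS36 (2.21), CHS1 (2.20) and ENA2 (2.13), higher in glucose, and HXT7 (-5.71), HXT6 (-5.55), MTH1 (-5.06), RGI1 (-4.67), RGI2 (-4.37), HXT4 (-4.08), AHT1 (-3.78), HXT2 (-3.75), MRK1 (-3.38) and PHO12 (-3.34), lower in glucose.

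Relative to each array's own genes, ribosome biogenesis genes fell further in glucose than in sorbitol, while general stress genes rose about as far in both. Whether this is a matter of scaling stays open: with spike-in scaling the list's median difference was -0.0346 in place of -1.25 (medians -2.60 and -2.78 in sorbitol and glucose), and general stress genes then rose further in glucose (1.91 and 2.86). The list's difference did not hang on loess alone, since the smaller of its values with median centring and with the scanner software's signals was -1.09, but both of these also centre each array on its own genes. The glucose to sorbitol ratio of medians was 2.12 for ribosome biogenesis (bootstrap 95% interval over genes 1.72 to 2.63) and 0.92 for general stress genes (0.81 to 1.20). With spike-in scaling the ratios were 1.07 (0.96 to 1.18) and 1.5 (1.26 to 2.40). With each scaling taken alone the intervals of the 2 lists did not overlap. The larger ratio changed list between the scalings, however. A scaling between the 2, which was not tested, could give both lists 1 ratio, so a single scale factor stays open. The intervals are over genes and do not measure the spread between arrays. With the scaling open, a stronger lowering of ribosome production in glucose is not shown in absolute terms, and no biological explanation was tested.

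The spike-in controls, which none of the planned comparisons used, were brighter relative to yeast genes in the stressed samples. After averaging over the dye orientations the offset of the 10 controls was 1.36 (log2, 2.56-fold) in sorbitol and 0.14 in glucose, against 1.66 and 0.48 by the software's own fit in the file headers. A dye or spike-mix bias common to all arrays cancels between the dye orientations and makes neither offset. A bias varying between arrays by as much as the residual is argued against for sorbitol, where the offset was 47.9 standard errors from 0 (1 residual degree of freedom), and stays open for glucose, where it was 4.96. Unequal amounts of added control in a sample cannot be told apart from less messenger RNA per µg of total RNA in stressed cells: both shift all controls alike, and the sorbitol offset had an SD of only 0.12 over the 10 controls.

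Replicates of a stress differed from each other in the same genes in both stresses, with a correlation across genes of 0.70 between the deviations. A dye effect tied to the probe's base composition is argued against, since base counts gave an R2 of 0.00243. Dye bias left in the brightest genes is a candidate explanation: a spline of mean signal gave an R2 of 0.279, and the median shared deviation was 0.84 (log2, replicate 1 minus the mean) in the brightest 2% of genes and -0.02 in the dimmer 90%. In the dimmer 90% the deviations still had a correlation of 0.44. A stronger response in replicate 1 (R2 0.0277), differences between the cultures or a dye effect of single genes stay open for that part. The replicate number and the dye orientation coincide in both stresses, so these cannot be told apart. No biological explanation was tested here.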

How the results depend on the processing

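Of 231 values of named genes, 135 kept their direction and their side of the threshold under every alternative run for them, as did 24 of 42 list calls while camera kept its preset correlation. Not all were run for each value: the series matrix gave 212 of the 231, fitting each stress alone 163 and probes of 1 gene 224, the 2-fold minimum was applied to counts only, and robust eBayes was not run for lists. The counts of genes changed by sorbitol and by glucose stayed within 1.5 times except as given here, and the correlation of the responses stayed between 0.73 and 0.78. Spike-in scaling shifts all genes of an array alike and the replicate block leaves the stress means unchanged, so neither could change this correlation. Asking for a 2-fold change as well left 1696 genes in sorbitol, 1767 in glucose and 796 for the difference. A large effect on the difference came from median centring in place of loess, with which limma called 0 genes (1801 at an unadjusted p under 0.05), against 1363; the cause was not tested. With an estimated correlation camera called 0 lists in each comparison (0 at an unadjusted p under 0.05), and fry called 20 in sorbitol, 22 in glucose and 0 for the difference (11 at an unadjusted p under 0.05). Of camera's calls fry shared 12 of 15 in sorbitol, 15 of 17 in glucose and 0 of 10 for the difference. Those it did not share were the ribosomal proteins, iron regulon and proteasome in sorbitol (fry adjusted p = 0.305, 0.0943 and 0.0707). In glucose they were the ribosomal proteins and the trehalose and glycogen list (fry adjusted p = 0.158 and 0.114). Leaving out each array in turn left between 1969 and 4103 genes for sorbitol, between 3203 and 3330 for glucose and between 67 and 1083 for the difference. Each time 1 stress kept a single array of 1 dye orientation, assumed to vary like the others, so a dye effect no longer cancelled. The lowest value for the difference was without sorbitol replicate 2, and 167, 870 and 1083 genes were called without sorbitol replicate 1, glucose replicate 2 and glucose replicate 1. Between 11 and 17 lists then differed between the stresses, against 10, between 15 and 19 were called in sorbitol and between 16 and 19 in glucose. With the spike-in scaling, chosen after seeing the data, 4997 genes differed, and 645 of these were called in the same direction without it. In sorbitol 930 genes called higher were then called lower, and for the difference 58 called lower were then called higher.

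With the replicate number as a block, which in this design is the same as a dye term per gene, 2841 genes differed between the stresses, among them all 1363 called without it, and 4669 and 4664 were changed by sorbitol and glucose. The labels give both stresses replicates 1 and 2, but with 2 pairs the numbers are not shown to pair the cultures, and the deviations of same-numbered arrays had a correlation of 0.70 across genes. The block kept all 42 list calls. The slide as a block was not run, since all arrays lay on 1 slide, and fitting each stress alone gives no test of the difference.

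Spike-in scaling turned these sorbitol values: RPL15B (-0.41), PRE4 (-0.56) and PUP2 (-0.77), each called higher without it and lower with it, CHA1 (-1.15), called only with it, and PRE2 (-0.31), no longer called. It turned the differences of RTC3 (0.90), HSP12 (0.51), PTC2 (0.41), APJ1 (0.13), MRPL25 (0.0717), MRPL15 (0.0806) and RPN4 (0.16), none called with it. List medians that turned were those of oxidative stress (-0.41), the tricarboxylic acid cycle (-0.77), the respiratory chain (-0.96), sporulation (-0.60) and the proteasome (-1.06) in sorbitol, and of the mitochondrial ribosome (0.74), RNA polymerases I and III (0.60), sulfur assimilation (0.59) and the G2 and M phases (0.50) for the difference. All genes moved alike, to medians of -1.36 and 1.16. Relative to the other genes, camera kept the direction and call of most of these lists. That is no separate support, since their log ratios relative to those genes had not moved. The calls of the tricarboxylic acid cycle, the proteasome and the mitochondrial ribosome were lost.

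Under the other alternatives direction changed only for genes that were not called in the comparison. With median centring CHA1 stood at -0.13 in sorbitol and the difference of GPP2 at -0.14. Leaving out arrays in turn, the lowest and highest differences were -0.11 and 1.68 for GPD1, -0.44 and 0.99 for GPP2, -0.44 and 1.15 for CTT1, -0.87 and 0.24 for RTC3, and -2.04 and 0.63 for HSP12, each end reached without 1 of the glucose arrays. Without sorbitol replicate 1 that of HSP12 was 0.08. Of these, GPD1 and CTT1 were called at their highest value. The cause was not tested. Signal over background, at least 108 at the median, did not limit most genes: the strict filter kept 6057 of 6184 genes and 1312 of the differences. The HOT1 signal stayed at background after background subtraction and by percentile, with 0 of 8 channels above the limit in each.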

Other observations

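The genes and groups in this part, and all tests in it except that of the trehalose and glycogen list, were chosen after their values were seen. The groups of thiamine synthesis, endoplasmic reticulum folding and amino acid breakdown were tested first. The other groups were added once those results and the genes moving in opposite directions were known, and the adjustment was then made over all 6. With it the amino acid breakdown genes lost a call in sorbitol (unadjusted p = 0.0119, adjusted p = 0.0715), while in glucose they were called up (10 of 15 rose, 0 fell, adjusted p = 0.00744, adjusted p = 0.29 with an estimated correlation). The rule for when a group counts as not differing was also reworded then, so that members called both ways leave it undecided. Relative to the array's own genes, genes for the use of maltose and sucrose were split between the stresses. Of 14 such genes 8 rose in sorbitol and 3 fell, while in glucose 1 rose and 10 fell, and 10 were called lower in glucose than in sorbitol and 1 higher. SUC2, the invertase, stood at 1.52 in sorbitol and at -0.68 in glucose, the maltose permease gene MAL31 at 1.85 and -0.58, and the maltase gene MAL12, whose probe is annotated to more than 1 gene, at 1.36 and -0.69. For the difference camera gave an adjusted p = 0.00118 over the 6 groups tested here, with an adjusted p = 0.28 with an estimated correlation. The group was called down in glucose (adjusted p = 0.0188, and 0.29 with an estimated correlation) and was not called in sorbitol (adjusted p = 0.221). Of its probes 6 are annotated to more than 1 gene, so its members are not all separate measurements. The group's values are given without spike-in scaling, which lowers all sorbitol values by 1.36 and all glucose values by 0.14. A rise in sorbitol smaller than 1.36 turns to a fall with it. The trehalose and glycogen list was not called as differing (camera adjusted p = 0.258), with 6 of 20 members lower in glucose and 14 not passed. With spike-in scaling 11 members were higher and 2 lower (median 0.86, against 1.16 for all genes). Camera then called the list down (adjusted p = 0.000498), though relative to all genes its log ratios had not moved. The 6 were GLC3, the glycogen branching enzyme (-3.04), the phosphorylase gene GPH1 (-2.42), GSY1, a glycogen synthase (-2.31), GAC1 (-2.13), GLG1, a glycogenin (-2.08), and PIG2 (-1.08). In sorbitol GLC3, GPH1, GSY1, GLG1 and PIG2 rose (2.69, 2.51, 2.12, 2.04 and 1.93) and GAC1 was not called. The trehalose synthesis genes TPS1 and TSL1 differed by -0.03 and -0.14 and were not called.

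Thiamine synthesis genes were higher in glucose (5 of 20 higher, 1 lower, median difference 0.32, camera adjusted p = 0.0147, adjusted p = 0.28 with an estimated correlation), with 6 of the probes annotated to more than 1 gene. Of 9 mitochondrially encoded genes 3 were lower in glucose and none higher (camera adjusted p = 0.0162, adjusted p = 0.60 with an estimated correlation). COB stood at 1.23 in sorbitol and -0.79 in glucose, and OLI1 at 1.62 and -0.60. Genes with a probe within 15 kilobases of the outermost probe of a chromosome arm were not called as a group and went both ways (21 of 228 higher, 38 lower, adjusted p = 0.342), which leaves a common shift undecided. Some open reading frames near chromosome ends that share probes, such as YHL049C (1.64 in sorbitol and -1.10 in glucose) and YFL065C (1.60 and -1.06), moved in opposite directions. Neither endoplasmic reticulum folding genes (2 of 21 higher, 4 lower, adjusted p = 0.554) nor genes of arginine and aromatic amino acid breakdown (4 of 15 higher, 2 lower, adjusted p = 0.383) were called as differing, and members of both went both ways. KAR2, the main chaperone of the endoplasmic reticulum, stood at -0.54 in sorbitol and 1.30 in glucose, and EUG1, a protein disulfide isomerase, at 0.63 and -0.77. All values in this paragraph are relative to the array's own genes. Spike-in scaling lowers every sorbitol value by 1.36, which would put COB and EUG1 below 0 in both stresses. OLI1, YHL049C, YFL065C and KAR2 would keep opposite signs.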
